A study of Mus musculus with 16 samples.

How the data were processed

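The labels describe hippocampus from male C57BL/6 mice in 4 groups: WT on regular water, WT on fructose, BgnKO on regular water and BgnKO on fructose, with 4 libraries each. Per the labels' protocols, total RNA was extracted with a Qiagen AllPrep kit, polyadenylated RNA was selected, complementary DNA was made with random hexamers, fragments of 200 to 400 base pairs were kept, and libraries were sequenced on an Illumina HiSeq and demultiplexed with CASAVA 1.8.2. Per the submitters' processing notes, reads were aligned to mm10 with TopHat and Bowtie and quantified with Cufflinks and Cuffdiff. The notes give no versions, strand setting, annotation or normalization.

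The values used are the FPKM that the authors deposited, in 1 table with 27670 loci and a value for each of the 16 libraries. The table also holds 4 columns of group FPKM, which were checked to be within 0.1 percent of the replicate means for at least 99.7% of loci above 0.5 FPKM and were not used further. FPKM carries no depth: whole-read steps could be seen in 41.9 to 53.2% of low values at best in replicates 2 to 4 and in 9.36 to 16.4% in replicate 1, so read numbers were not recovered and no counting interval is given. Of the loci, 4269 have no gene name and take 46.8 to 70.4% of the FPKM of a library. They were left out of the tests and are given in the closing section. The other loci carry 22572 names. Where several loci share a name (711 names) their FPKM were summed, a choice made before any contrast was computed. A name that joins several genes (659 entries) was kept as 1 entry. The sum over named loci was 342721 to 376209 FPKM per library. Between any 2 libraries the root mean square log2 difference was 0.179 to 0.560, so no library is a copy of another.

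Gene positions came from GENCODE vM21 (GRCm38, the same assembly as mm10) and then RefSeq GRCm38.p6, matched by name, and are 1-based. A position was found for 95.5% of tested genes and a transcript length for 95.4%. The strand of 19626 genes with 1 locus could be read from the order of the loci and matched the annotation for 99.8%. The share of FPKM on the strand opposite to the annotated one was taken over 446 genes with loci on both strands.

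Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(FPKM + 1), for the 12648 genes with a mean of at least 1 FPKM over the 16 libraries. The model had 4 group means and no block, as fixed beforehand. For fructose vs water the deviations of same-number libraries from their group means had correlations over 0.1 in every pair. They were 0.118 to 0.699 in WT and 0.197 to 0.612 in BgnKO. From the means of replicates 2 to 4 alone the correlations were 0.00 to 0.14 and -0.04 to 0.31. They thus rest on replicate 1, and a pairing of the others is not shown. For BgnKO vs WT they were -0.04 to 0.69 on water and 0.09 to 0.75 on fructose. The comparisons were BgnKO against WT on water and on fructose, fructose against water in WT and in BgnKO, the interaction, and each factor averaged over the other. P-values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Group SDs are of FPKM, and SE is the moderated standard error of the log2 fold. Libraries on a side are the libraries of the first group that lie on the side of the difference relative to the mean of the reference group on the same drink or of the same genotype. Bgn was also tested by exact permutation of its FPKM. The groups, comparisons, filter, tests, lists, named-gene rule and most alternative settings were fixed before the data were examined.

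Before the data were examined 51 lists were fixed from general knowledge, 33 of genes and 18 of markers of cell types or neighbouring tissues. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, which gave 47 lists, 16 of them marker lists. The mitochondrially encoded genes, sex-specific genes, blood cell markers, and hypothalamus and pituitary markers had fewer members past the filter and were not tested. Camera compares the members with all other genes. Calls with the preset correlation assume that members vary almost independently, and with a correlation estimated from the data 0 lists passed in any of the 7 comparisons. Members were also adjusted over their list alone.

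The text names Bgn, up to 10 genes with the highest and 10 with the lowest log2 fold among those called, up to 4 members of each described list by unadjusted p, and 12 genes fixed beforehand (Bgn, Fmod, Dcn, Ttr, Igf1, Igf1r, Bdnf, Txnip, Khk, Slc2a5, Fkbp5 and Fos). Khk was not found in the table under that name. Where fewer than 10 genes were called, genes of smallest unadjusted p fill the number, as values only. Genes whose names are Gm plus digits or end in Rik are counted and not named. Some genes that the rule selects are not reported here. Genes listed at 0 in a whole group are given as library values.

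Tests on simulated data used normal noise of each gene's residual SD around its mean. Log2 changes of 0.5, 1, 2 and 4 were added together, to 50 of 12648 genes each. Genes vary independently there, unlike in tissue, so the list results below do not test the preset correlation. Of the 50 genes, the percentages recovered were 54, 96, 100 and 98 for WT fructose vs WT water, 62, 90, 100 and 98 for BgnKO fructose vs BgnKO water, 62, 94, 100 and 98 for BgnKO water vs WT water, 66, 90, 100 and 98 for BgnKO fructose vs WT fructose, and 82, 100, 100 and 98 for BgnKO vs WT averaged over drinks. False calls numbered 8, 10, 20, 9 and 15. No list was called before a change was added, and one with an added change of 0.3 was recovered in all 5 comparisons.

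The alternative settings fixed beforehand were a pseudocount of 0.1, no filter (19036 genes), a filter of 5 FPKM (9029 genes), median-ratio rescaling, quantile normalization, no mean-variance trend, array weights, replicate number as a block, a fit of only the groups compared, leaving out each library in turn, the choroid plexus score as a covariate, fry and an estimated correlation. Those added after the data were seen were a term for replicate 1, replicates 2 to 4 only, leaving out genes listed at 0 in a whole group, leaving out a doubted pair of libraries, marker scores as covariates, loci kept apart, and some of the earlier settings for more results. Random splits and lists used seed 20, with 100 splits where not all could be run and 10000 random lists. Other computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.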

Results

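Messenger RNA from the hippocampus of male C57BL/6 mice was measured in 16 libraries, 4 in each of 4 groups. The mice were wild type (WT) or carried a knockout of Bgn on the X chromosome (Bgn0/- in the labels, BgnKO here), and drank regular water or water with 15% fructose (w/v) for 6 weeks from 3 months of age. Bgn encodes biglycan, a small leucine-rich proteoglycan of the extracellular matrix. The comparisons that follow from this design are the effect of the knockout on each drink, the effect of fructose in each genotype, the interaction of both, and the effect of each factor averaged over the other. The deposited values are FPKM (fragments per kilobase of transcript, scaled to library size in a way that the notes do not give). The depth of each library is therefore unknown and no counting interval can be given. Between 12343 and 12885 named genes reached 1 FPKM per library, and the upper quartile of FPKM lay between 13.8 and 14.7. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples, which may be technical.

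Replicate 1 of each group stood apart from replicates 2 to 4. Over 446 genes with a locus on both strands, the opposite strand took 14.2 to 14.7% of the FPKM in the replicate 1 libraries and 26.6 to 29.7% in the other 12. This technical split runs across all 4 groups, so results are also given with a term for it and in replicates 2 to 4 alone. The replicate 1 libraries alone hold 1 library per group, so 2 groups cannot be compared in them.

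Bgn (mm10, chromosome X, 73483602 to 73495933, plus strand) was lower in the knockout. On water its FPKM, summed over a pair of loci on opposite strands, was 6.62 ± 1.45 (SD, n = 4) in BgnKO and 15.9 ± 6.47 (SD, n = 4) in WT, with a 2-sided exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow. On fructose it was 6.39 ± 0.932 (SD, n = 4) against 16.1 ± 7.37 (SD, n = 4), with an exact p of 0.114. Over both drinks BgnKO held 40.6% of the WT level (6.50 ± 1.14 against 16.01 ± 6.42, SD, n = 8 each, exact permutation p = 0.00109). The 8 BgnKO libraries lay between 4.46 and 7.60 FPKM. The library labelled WT fructose replicate 1, at 5.42 FPKM, lay inside that range, above both BgnKO replicate 1 libraries (4.46 and 5.02), and on the plus-strand locus alone, at 4.00, between them (3.59 and 4.39). In 2 genes looked at after the values were seen it lay with WT: Ndufs5 was 14.0 FPKM (0 to 0.216 in BgnKO) and Bex4 14.9 (2.79 to 5.09 in BgnKO). In replicates 2 to 4 the values were 7.09 ± 0.341 and 18.8 ± 4.31 (SD, n = 6 each, exact permutation p = 0.00216), and in replicate 1 they were 4.74 and 7.68 (n = 2 each, exact p = 0.333). Which part of the gene is deleted is not given in the sources used here, so signal from an undeleted part cannot be ruled out.

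**Figure D1:**
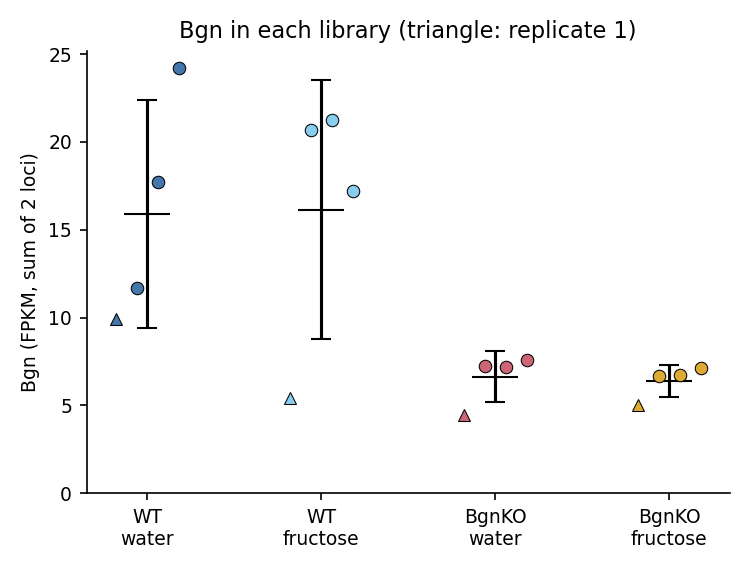
Bgn FPKM (sum of 2 loci) in each of the 16 libraries by group, with the mean and SD of each group of 4; triangles mark replicate 1. All 8 BgnKO libraries lie at or under 7.60 FPKM.

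In mice drinking water, the knockout had lower Ndufs5, Bex4, Ccl25 and Lyplal1 and higher Hdhd3, Alad, Kcnk2 and Serpina3 transcripts than WT. Genes of cholesterol biosynthesis and immediate early genes, which neuronal activity induces, lay lower as groups. Ndufs5, a subunit of mitochondrial complex I (chromosome 4, 123712710 to 123718202), fell from 11.5 ± 1.62 to 0.106 ± 0.0105 FPKM (SD, n = 4 each), a log2 fold change of -3.49 (SE 0.10, limma adjusted p = 2.64e-12, lower in 4 of 4 BgnKO libraries). BC002163 on chromosome 16 rose from 109.6 ± 7.59 to 221.4 ± 11.0 FPKM (SD, n = 4 each), a log2 fold of 1.01 (SE 0.07, limma adjusted p = 3.77e-07). Reads could go to either gene, so both are uncertain, BC002163 more. It shares 81.0% of its distinct 31-base words with Ndufs5, which shares 26.5% of its own.

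Limma called 49 of 12648 genes at an adjusted p under 0.05 on water, 22 higher and 27 lower in BgnKO, and every called gene named here lay on its side of the WT mean in 4 of 4 BgnKO libraries. Among the genes that rose, Hdhd3 had a log2 fold of 1.24 (SE 0.14, limma adjusted p = 0.000157), and its neighbour Alad, an enzyme of heme synthesis, 1.06 (SE 0.13, limma adjusted p = 0.000628). The merged entry for Serpina3h, Serpina3k and Serpina3n, related serine protease inhibitors whose reads cannot be separated here, rose by 1.20 (SE 0.10, limma adjusted p = 7.61e-06). Kcnk2, a background potassium channel, rose by 0.69 (SE 0.08, limma adjusted p = 0.000113), from 8.24 ± 0.433 to 14.0 ± 1.33 FPKM (SD, n = 4 each). Stxbp2 rose by 0.76 (limma adjusted p = 0.00176) and Gemin8 by 0.76 (limma adjusted p = 0.00939). Rmrp, the RNA of RNase MRP, had a log2 fold of 2.03 (limma adjusted p = 0.0339), Fam227b 0.90 (0.0397) and Cbr3 0.66 (0.0471). Among the genes that fell, X-linked Bex4 changed by -1.64 (SE 0.12, limma adjusted p = 1.40e-06), the chemokine Ccl25 by -1.11 (SE 0.09, limma adjusted p = 5.55e-06) and Lyplal1 by -0.82 (SE 0.07, limma adjusted p = 3.89e-06). D8Ertd82e had -0.87 (limma adjusted p = 6.45e-06), Snapc1 -0.78 (7.17e-05), the merged entry with Hjurp -1.40 (0.0471) and the transcription factor Egr1 -0.95 (0.0471). The ribosomal RNA precursor Rn45s was listed at 0 in all 8 BgnKO libraries and at 373 to 1085 FPKM in the 8 WT libraries. Bgn itself changed by -1.09 (SE 0.34) with an adjusted p of 0.370, 0.0193 with the term for replicate 1 and 0.0166 in replicates 2 to 4. Of the other genes fixed beforehand, Fos had -1.08 (adjusted p = 0.2998), Bdnf -0.29, Fmod 0.76, Dcn 0.20, Ttr -0.32, Igf1 0.12, Igf1r 0.09, Txnip -0.12, Slc2a5 -0.13 and Fkbp5 0.08, none past the threshold.

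The 49 genes became 126 with a term for replicate 1, all 49 kept in direction, and 79 in replicates 2 to 4, 39 of the 49 kept. Without WT water replicate 2 or 4, or BgnKO water replicate 2 or 3, limma called 30, 30, 32 and 31 genes. The calls of Rmrp, Fam227b, Cbr3, Egr1 and the entry with Hjurp ended in replicates 2 to 4 (limma adjusted p = 0.0743, 0.0999, 0.0961, 0.0984 and 0.0613) and in fits that left out 1 library. Without the filter on low FPKM they had an adjusted p of 0.0580, 0.0531, 0.0658, 0.0661 and 0.0710, and with a filter of 5 FPKM Cbr3, Egr1 and the entry with Hjurp had 0.0510 each. With a pseudocount of 0.1 Fam227b had 1.73 (adjusted p = 0.213; 0.0525 with quantile normalization) and the entry with Hjurp -1.67 (0.0711). Ndufs5 had -5.81 and stayed called. The calls of Fam227b (0.73, 0.0767) and Egr1 (-0.99, 0.0748) ended with choroid plexus, meninges and astrocyte scores. Myelin, astrocyte and microglia scores ended those of Rmrp (1.99, 0.206), Fam227b (0.78, 0.231) and Cbr3 (0.60, 0.165). Without the library labelled WT fructose replicate 1 and BgnKO fructose replicate 4 those of Fam227b, Cbr3 (0.0579 each), Egr1 (0.0516) and the entry with Hjurp (0.0641) ended. The adjusted p of Rmrp in BgnKO water vs WT water was above 0.05 without WT water replicate 1 (0.0964) or 2 (0.130), WT fructose replicate 2 (0.0539) or 3 (0.0521), BgnKO water replicate 1 (0.0749), 2 (0.0554), 3 (0.0938) or 4 (0.131), or BgnKO fructose replicate 3 (0.0523). For Fam227b this was so without WT water replicate 1 (0.0821), 2 (0.128), 3 (0.0681) or 4 (0.130), WT fructose replicate 2 (0.0539), BgnKO water replicate 1 (0.0604), 3 (0.132) or 4 (0.133), or BgnKO fructose replicate 4 (0.05001). For Cbr3 it was so without WT water replicate 1 (0.0821), 2 (0.103), 3 (0.125) or 4 (0.167), WT fructose replicate 2 (0.0529), 3 (0.0731) or 4 (0.0702), BgnKO water replicate 1 (0.0749), 3 (0.0997) or 4 (0.114), or BgnKO fructose replicate 3 (0.0696) or 4 (0.0570). Egr1 lost its call without WT water replicate 1 (0.0561), 2 (0.132), 3 (0.166) or 4 (0.158), WT fructose replicate 2 (0.0635), BgnKO water replicate 1 (0.132), 2 (0.168) or 4 (0.133), or BgnKO fructose replicate 3 (0.0708) or 4 (0.0563), and with median-ratio rescaling (0.0508) or quantile normalization (0.0541). The entry with Hjurp lost it without WT water replicate 1 (0.116), 2 (0.132), 3 (0.128) or 4 (0.124), the library labelled WT fructose replicate 1 (0.0518), 2 (0.0691), 3 (0.0696) or 4 (0.0702), BgnKO water replicate 2 (0.188) or 3 (0.163), or BgnKO fructose replicate 1 (0.0518), 3 (0.0541) or 4 (0.0569).

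All 22 tested genes of cholesterol biosynthesis lay lower in BgnKO on water, with a median log2 fold of -0.24 and a lower mean in 4 of 4 libraries. The list fell (camera adjusted p = 4.14e-17; adjusted p = 0.0600 with an estimated correlation). None of its members passed over all genes and 9 passed adjusted over the list alone. Stard4 had a log2 fold of -0.51 (SE 0.13), Fdps, which makes farnesyl pyrophosphate, -0.32 (SE 0.08), and the squalene synthase Fdft1 -0.28 (SE 0.08). Of 21 immediate early genes 20 lay lower, with a median of -0.44 in 4 of 4 libraries, and the list fell (camera adjusted p = 2.63e-15; adjusted p = 0.117 with an estimated correlation). Its members Nr4a3 (-0.53, SE 0.10, limma adjusted p = 0.0358) and Egr1 passed over all genes, and 8 passed adjusted over the list alone. Egr4 had -0.72 (SE 0.16) and Junb -0.66 (SE 0.15).

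Markers of other cell types and tissues moved with the genotype on water. All 17 markers of meninges and fibroblasts lay higher in BgnKO (median 0.44, higher in 4 of 4 libraries, camera adjusted p = 3.05e-05; adjusted p = 0.749 with an estimated correlation), among them Asgr1 0.62, Ogn 0.44, Foxd1 0.30 and Col1a2 0.66, and 0 passed over all genes or adjusted over the list alone. Of 17 astrocyte markers 16 lay higher (median 0.11, camera adjusted p = 0.000786; adjusted p = 0.749 with an estimated correlation), with Gfap at 0.36 and Aqp4 at 0.26. This call ended without WT water replicate 1 (adjusted p = 0.0754) or BgnKO water replicate 4 (0.480). In all 13 of 47 tested lists passed with the preset correlation of camera and 0 with an estimated one. Without WT water replicate 1, BgnKO water replicate 2 or BgnKO water replicate 4 the 13 became 6, 7 and 5. With the term for replicate 1 there were 9, and 12 in replicates 2 to 4, with cholesterol, immediate early, meningeal and astrocyte genes among them each time. Fry, which tests whether the genes of a list move one way and does not compare them with other genes, called 1, cholesterol biosynthesis (adjusted p = 0.0155).

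On fructose Ndufs5, Bex4 and Ccl25 were again lower in the knockout, and of the 49 genes called on water 42 were also called on fructose, in the same direction. Ndufs5 changed by -3.67 (SE 0.10, limma adjusted p = 7.07e-13), Bex4 by -1.82 (SE 0.12, limma adjusted p = 3.67e-07) and Ccl25 by -1.06 (SE 0.09, limma adjusted p = 6.92e-06), each lower in 4 of 4 BgnKO libraries. Markers of astrocytes and genes of TGF-beta and BMP signalling lay higher as groups in BgnKO, and immediate early and cholesterol genes lower. Egr1 fell from 92.8 ± 31.5 to 38.5 ± 6.91 FPKM (SD, n = 4 each), a log2 fold of -1.20 (SE 0.19, limma adjusted p = 0.00374).

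Limma called 475 genes on fructose, 206 higher and 269 lower in BgnKO, and every named call lay on its side of the WT mean in 4 of 4 BgnKO libraries. Rmrp rose by 2.23 (SE 0.39, limma adjusted p = 0.00692), the beta-defensin Defb11 by 1.92 (SE 0.37, limma adjusted p = 0.0121), Zc3h7a by 1.69 (SE 0.31, limma adjusted p = 0.00974) and Filip1l by 1.48 (SE 0.26, limma adjusted p = 0.00692). Fam227b rose by 1.46 (limma adjusted p = 0.000333), the ribosomal protein gene Rplp0 by 1.33 (0.0258), the mitochondrial leucyl-tRNA synthetase Lars2 by 1.29 (0.00486) and Scoc by 1.27 (0.0365). The cytochrome c oxidase subunit Cox6a2 changed by -1.32 (limma adjusted p = 0.0188), the transcription factor Rreb1 by -1.23 (0.00169), the entry with Hjurp by -1.18 (0.0338) and the nuclear receptor Nr4a1 by -1.04 (SE 0.20, limma adjusted p = 0.0104). Rn45s, described above, Camk2a, Rprl3 and Eif3j2 also passed, but each was listed at 0 in a whole group. Eif3j2 was listed at 0 in the 4 BgnKO fructose libraries and at 1.235 to 3.93 FPKM in the WT fructose libraries, and Rprl3 at 0 in 3 of the 4 WT fructose libraries. Bgn had -1.07 (SE 0.34) with an adjusted p of 0.0869, 0.00591 with the term for replicate 1 and 0.00242 in replicates 2 to 4. Bdnf had -0.34 (SE 0.15, adjusted p = 0.206, 0.0176 with the term for replicate 1), Fos -0.65, Ttr 1.44 (SE 0.83), Fmod 0.58, Dcn 0.47, Igf1 0.06, Igf1r 0.17, Txnip 0.14, Slc2a5 -0.23 and Fkbp5 0.06.

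The 475 genes became 2190 with the term for replicate 1 and kept all 475 in direction, and 1377 in replicates 2 to 4 with 425 kept. Limma called 282 genes with the choroid plexus score as a covariate, 31 with choroid plexus, meninges and astrocyte scores, 20 with myelin, astrocyte and microglia scores, and 137 without the library labelled WT fructose replicate 1 and BgnKO fructose replicate 4. Without WT fructose replicate 2, 3 or 4 limma called 178, 259 and 147 genes, and without BgnKO fructose replicate 1, 3 or 4 it called 940, 243 and 166. The call of Rplp0 in BgnKO fructose vs WT fructose ended without BgnKO fructose replicate 3 (0.0673) or 4 (0.0858). Cox6a2 lost its call without WT fructose replicate 2 (0.0569) or 4 (0.0702), or BgnKO fructose replicate 4 (0.0699). Scoc lost it without WT fructose replicate 2 (0.107), 3 (0.0963) or 4 (0.114), or BgnKO fructose replicate 1 (0.0525), 2 (0.0539), 3 (0.0749) or 4 (0.0695). The entry with Hjurp lost it without the library labelled WT fructose replicate 1 (0.0700), 2 (0.0768), 3 (0.0567) or 4 (0.0911), or BgnKO fructose replicate 2 (0.0566) or 4 (0.0665). Among the calls above, 13 ended with choroid plexus, meninges and astrocyte scores: Rmrp (log2 fold 2.84, adjusted p = 0.128), Defb11 (0.97, 0.276), Zc3h7a (1.70, 0.182), Fam227b (1.37, 0.0831), Rplp0 (1.16, 0.279), Lars2 (1.66, 0.0831), Scoc (1.76, 0.114), Cox6a2 (-1.04, 0.272), Rreb1 (-1.21, 0.137), Egr1 (-1.15, 0.171), Nr4a1 (-1.20, 0.169), Eif3j2 (adjusted p = 0.262) and the entry with Hjurp (-1.76, 0.134). The same 13 and Filip1l (2.08, 0.146) ended with myelin, astrocyte and microglia scores. Without that pair of libraries Defb11 (0.0716), Rplp0 (0.0770), Eif3j2 (0.0716) and the entry with Hjurp (0.118) lost their calls. The choroid plexus score ended those of Cox6a2 (0.0518) and the entry with Hjurp (0.112). Without the filter on low FPKM the calls of Scoc (0.0562) and the entry with Hjurp (0.0521) ended. With a pseudocount of 0.1 Ndufs5 had -6.23, Fam227b 2.96 and Defb11 2.97, all still called. That of Filip1l also ended with quantile normalization (0.0904).

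All 17 astrocyte markers lay higher in BgnKO on fructose (median 0.42, higher in 4 of 4 libraries), and the list rose (camera adjusted p = 9.69e-09; adjusted p = 0.4997 with an estimated correlation). Over all genes 4 members rose, and 12 adjusted over the list alone. They were the growth factor receptor Fgfr3 (0.62, SE 0.12, limma adjusted p = 0.0159), the gap junction gene Gja1 (0.42, SE 0.10, 0.0297), the filament gene Gfap (0.58, SE 0.15, 0.0409) and the water channel Aqp4 (0.54, SE 0.14, 0.0480). Of 21 genes of TGF-beta and BMP signalling 17 lay higher (median 0.31, 4 of 4 libraries, camera adjusted p = 0.000212; adjusted p = 0.361 with an estimated correlation), and 5 rose over all genes as well as adjusted over the list alone. They included Smad6 (0.72, SE 0.11, limma adjusted p = 0.00361), Id3 (0.83, SE 0.15, 0.00977), Id1 (0.68, SE 0.15, 0.0224) and Bmpr1a (0.39, SE 0.09, 0.0307). Smad6 and Id genes are known targets of BMP receptors. Of 15 genes of fatty acid oxidation and ketone metabolism 12 lay higher (median 0.26, 4 of 4 libraries, camera adjusted p = 0.00205; adjusted p = 0.361 with an estimated correlation), and 2 passed over all genes, Acadm (0.35, limma adjusted p = 0.0313) and Hadhb (0.39, 0.0468), and 5 adjusted over the list alone.

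Among 21 immediate early genes 18 lay lower on fructose (median -0.32, 4 of 4 libraries, camera adjusted p = 7.47e-05; adjusted p = 0.4997 with an estimated correlation). Over all genes 4 fell, Nr4a3 (-0.68, SE 0.10, limma adjusted p = 0.00277), Egr1, Nr4a1 and Egr2 (-0.91, SE 0.21, limma adjusted p = 0.0258), and 8 adjusted over the list alone. Of 22 cholesterol biosynthesis genes 17 lay lower (median -0.17, 4 of 4 libraries, camera adjusted p = 0.000543; adjusted p = 0.4997 with an estimated correlation). Over all genes 2 members fell, among them Fdft1 (-0.38, SE 0.08, limma adjusted p = 0.0195), and 8 adjusted over the list alone. Fdps had -0.30 (adjusted p = 0.0502). Of 26 genes of the presynaptic vesicle machinery 23 lay lower (median -0.14, camera adjusted p = 0.00631; adjusted p = 0.761 with an estimated correlation), with 1 call over all genes and 2 adjusted over the list alone. That list's call ended without BgnKO fructose replicate 4 (adjusted p = 0.0678 in BgnKO fructose vs WT fructose). Of 11 CA1 pyramidal cell markers 9 lay lower (median -0.26, camera adjusted p = 0.00500; adjusted p = 0.579 with an estimated correlation). With choroid plexus, meninges and astrocyte scores as covariates the calls of TGF-beta and BMP signalling (0.736 in BgnKO fructose vs WT fructose), fatty acid oxidation (0.889), cholesterol biosynthesis (0.144), the presynaptic list (0.441) and CA1 markers (0.850) ended, while immediate early genes kept theirs.

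Tissue markers moved with the genotype on fructose as well. All 27 choroid plexus markers lay higher in BgnKO (median 1.08, 4 of 4 libraries, camera adjusted p = 1.36e-07; adjusted p = 0.740 with an estimated correlation), yet 0 passed over all genes or adjusted over the list alone. Sostdc1 had 1.27 (SE 0.50, adjusted p = 0.161) and Wdr86 0.81 (SE 0.30, 0.131). The mean log2(FPKM + 1) of these markers was 1.75 in the library labelled WT fructose replicate 1, 3.24 to 3.68 in the other WT fructose libraries and 3.22 to 5.11 in BgnKO fructose. All 17 meningeal markers lay higher (median 0.47, 3 of 4 libraries, camera adjusted p = 0.00192; adjusted p = 0.761 with an estimated correlation), but this call ended without the library labelled WT fructose replicate 1 (adjusted p = 0.201 in BgnKO fructose vs WT fructose) or BgnKO fructose replicate 4 (0.0678). Without both libraries the calls of choroid plexus (0.241) and endothelial markers (0.107) ended too. Of 15 endothelial markers 14 lay higher (median 0.28, 3 of 4 libraries, camera adjusted p = 0.000311; adjusted p = 0.656 with an estimated correlation), and Itm2a rose (0.62, SE 0.15, limma adjusted p = 0.0322). With the preset correlation 23 of 47 lists passed, 15 without the library labelled WT fructose replicate 1 and 11 without BgnKO fructose replicate 4. With an estimated correlation 0 passed, and fry called 10. The lists described for this comparison kept their calls with the term for replicate 1 (22 lists in all) and in replicates 2 to 4 (25).

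Averaged over drinks, BgnKO had lower immediate early and cholesterol genes in all 8 libraries and higher astrocyte markers. On water their mean lay in the WT range in replicates 1 to 3. Ndufs5 changed by -3.58 (SE 0.07, limma adjusted p = 1.05e-14), Bex4 by -1.73 (SE 0.09, limma adjusted p = 4.01e-09) and Ccl25 by -1.08 (SE 0.07, limma adjusted p = 3.93e-08), each lower in 8 of 8 BgnKO libraries. The Serpina3h, Serpina3k and Serpina3n entry rose by 1.18 (SE 0.07, limma adjusted p = 5.72e-08) and Hdhd3 by 1.18 (SE 0.10, limma adjusted p = 2.39e-06), each higher in 8 of 8. Bgn fell by 1.08 (SE 0.24, limma adjusted p = 0.0168, 0.000398 with the term for replicate 1 and 0.000229 in replicates 2 to 4).

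Limma called 631 genes for the averaged genotype effect, 268 higher and 363 lower in BgnKO. Rmrp (2.13, limma adjusted p = 0.000322), Defb11 (1.66, 0.00187), Zc3h7a (1.36, 0.00216), Filip1l (1.20, 0.00166) and Fam227b (1.18, 4.49e-05) were higher in 8 of 8 libraries, and Snord15b (2.34, SE 0.64, limma adjusted p = 0.0464) in 7 of 8. Hmgn2, a nucleosome-binding protein, changed by -1.54 (SE 0.34, limma adjusted p = 0.0152), Cox6a2 by -1.23 (0.00213), the entry with Hjurp by -1.29 (0.00184) and Egr1 by -1.08 (SE 0.14, limma adjusted p = 0.000272), all lower in 8 of 8. Rn45s, Camk2a, Rprl3 and Eif3j2 passed with values listed at 0 in whole groups. Fos had -0.86 (SE 0.22, limma adjusted p = 0.0373), a call that ended in BgnKO vs WT averaged over drinks without WT water replicate 2 (0.0719), 3 (0.0560) or 4 (0.0726), WT fructose replicate 2 (0.0769) or 4 (0.0805), BgnKO water replicate 1 (0.0682) or 2 (0.0704), or BgnKO fructose replicate 2 (0.0594) or 4 (0.0748). The call of Snord15b ended in replicates 2 to 4 (0.0620) and without WT water replicate 1 (0.0712), 2 (0.0643) or 3 (0.0968), WT fructose replicate 2 (0.0615), 3 (0.0887) or 4 (0.0995), BgnKO water replicate 1 (0.0509), 2 (0.0668), 3 (0.0924) or 4 (0.0814), or BgnKO fructose replicate 1 (0.0547), 2 (0.0779) or 3 (0.0907). With choroid plexus, meninges and astrocyte scores the calls of Cox6a2 (-1.17, 0.0525), Fos (-1.15, 0.0705), Hmgn2 (-1.05, 0.191), Snord15b (3.45, 0.0583), Eif3j2 (0.0837) and Zc3h7a (1.36, 0.0502) ended, while standard errors grew by a median factor of 1.43. With myelin, astrocyte and microglia scores those of Bgn (-1.52, 0.212), Rmrp (2.26, 0.101), Defb11 (1.65, 0.170), Zc3h7a (1.64, 0.0706), Filip1l (1.60, 0.0504), Fam227b (0.96, 0.0763), Hmgn2 (-1.74, 0.368), Fos (-1.26, 0.192), Eif3j2 (0.381) and Snord15b (3.61, 0.262) ended. Without the filter on low FPKM those of Fos (0.0544) and Snord15b (0.0683) ended. The choroid plexus score ended that of Fos (0.0637). Without the library labelled WT fructose replicate 1 and BgnKO fructose replicate 4 Fos (0.0575) and Hmgn2 (0.0508) lost theirs. With a pseudocount of 0.1 Snord15b had 3.68 (adjusted p = 0.101), Ndufs5 -6.02, Fam227b 2.34 and Defb11 2.83. Bdnf had -0.32 (SE 0.11, adjusted p = 0.0997, 0.00374 with the term for replicate 1) and Igf1r 0.13 (0.150, 0.0421 with that term). Fmod had 0.67, Dcn 0.34, Ttr 0.56, Igf1 0.09, Txnip 0.01, Slc2a5 -0.18 and Fkbp5 0.07. The 631 genes became 2279 with the term for replicate 1, which kept all 631 in direction, and 1590 in replicates 2 to 4, which kept 568. With choroid plexus, meninges and astrocyte scores as covariates 553 genes were called, 173 of the 631 among them in the same direction, and with myelin, astrocyte and microglia scores 53. Without WT fructose replicate 4, or BgnKO fructose replicate 1 or 3, limma called 392, 1061 and 411 genes.

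**Figure D2:**
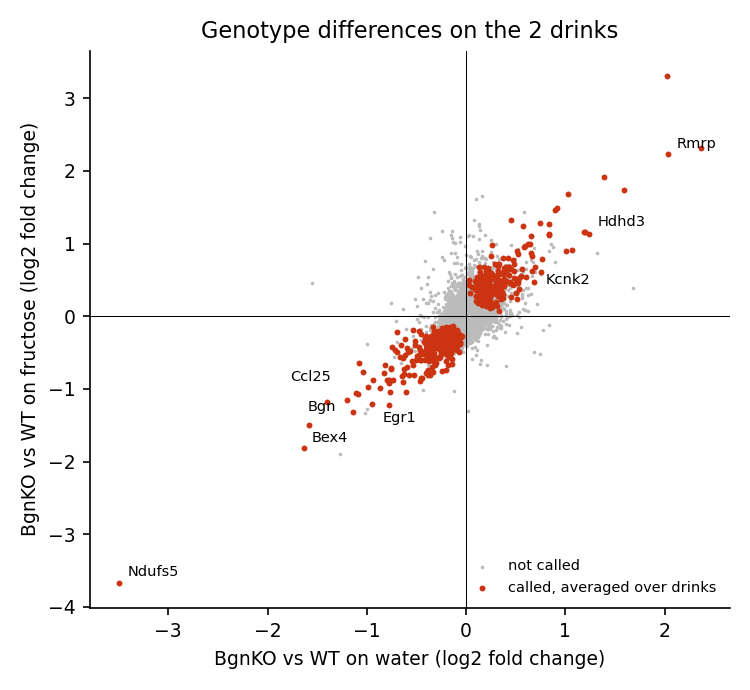
Log2 fold change of BgnKO against WT on log2(FPKM + 1) for each tested gene, on water (horizontal) and on fructose (vertical); red points are genes called in the averaged comparison, and genes listed at 0 in a whole group are left out. Ndufs5 lies at -3.49 and -3.67 and Bex4 at -1.64 and -1.82.

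Of 21 immediate early genes 9 fell over all genes in the averaged comparison and 13 adjusted over the list alone (median -0.39, 18 members lower, camera adjusted p = 7.29e-09; adjusted p = 0.296 with an estimated correlation). Nr4a3 changed by -0.60 (SE 0.07, limma adjusted p = 0.000169), Nr4a1 by -0.90 (SE 0.14, 0.00166) and Egr2 by -0.84 (SE 0.15, 0.00346). Of 22 cholesterol biosynthesis genes 9 fell over all genes and 14 adjusted over the list alone (median -0.19, 20 members lower, camera adjusted p = 7.29e-09; adjusted p = 0.293 with an estimated correlation). Fdft1 changed by -0.33 (SE 0.06, limma adjusted p = 0.00346), Fdps by -0.31 (SE 0.06, 0.00462) and Stard4 by -0.46 (SE 0.09, 0.00759). All 17 astrocyte markers lay higher (median 0.27, camera adjusted p = 2.43e-08; adjusted p = 0.448 with an estimated correlation), with 5 rising over all genes and 12 adjusted over the list alone. Fgfr3 rose by 0.42 (SE 0.09, limma adjusted p = 0.0122), Gfap by 0.47 (SE 0.10, 0.0161), Gja1 by 0.31 (SE 0.07, 0.0198) and Aqp4 by 0.40 (SE 0.10, 0.0326).

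Of 21 genes of TGF-beta and BMP signalling 5 rose and 1 fell over all genes, and 8 and 1 adjusted over the list alone (median 0.25, 18 members higher, 8 of 8 libraries, camera adjusted p = 0.000269; adjusted p = 0.293 with an estimated correlation). Smad6 rose by 0.51 (SE 0.08, limma adjusted p = 0.00194), Id3 by 0.54 (SE 0.11, 0.00934), Id2 by 0.29 (SE 0.06, 0.0169) and Bmpr1a by 0.25 (SE 0.06, 0.0359). The member that fell was the ligand Tgfb2 (-0.24, SE 0.07, limma adjusted p = 0.0498), named after its value was seen. In fatty acid oxidation and ketone metabolism 3 of 15 genes rose over all genes, and 4 rose and 1 fell adjusted over the list alone (median 0.16, camera adjusted p = 0.00488; adjusted p = 0.296 with an estimated correlation). Acadm rose by 0.24 (SE 0.06, limma adjusted p = 0.0266), Acadvl by 0.24 (SE 0.06, 0.0310) and Hadhb by 0.26 (0.0494). In fatty acid synthesis and lipid handling 3 of 20 rose over all genes and 5 adjusted over the list alone (median 0.05, 7 of 8 libraries, camera adjusted p = 0.0260; adjusted p = 0.784 with an estimated correlation), the regulator Srebf1 (0.38, SE 0.07, limma adjusted p = 0.00408), the stearoyl-CoA desaturase Scd1 (0.47, SE 0.09, 0.00796) and the cholesterol exporter Abca1 (0.27, SE 0.07, 0.0450). That list's call ended without any 1 of WT water replicate 1, the library labelled WT fructose replicate 1, BgnKO water replicate 4 or BgnKO fructose replicate 4 (adjusted p = 0.0750, 0.0791, 0.0533 and 0.0710 in BgnKO vs WT averaged over drinks). Of 26 presynaptic genes 23 lay lower (median -0.13, 8 of 8 libraries, camera adjusted p = 0.00533; adjusted p = 0.784 with an estimated correlation), and Unc13a, a vesicle priming factor, fell over all genes (-0.26, SE 0.06, limma adjusted p = 0.0164). With choroid plexus, meninges and astrocyte scores the calls of TGF-beta and BMP signalling (0.714), fatty acid oxidation (0.898), fatty acid synthesis (0.539) and the presynaptic list (0.261) ended, while cholesterol biosynthesis and immediate early genes kept theirs.

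Markers of meninges (all 17 higher, median 0.46, 7 of 8 libraries, camera adjusted p = 6.56e-05; adjusted p = 0.784 with an estimated correlation), choroid plexus (all 27 higher, median 0.51, 7 of 8 libraries, 0.000188; adjusted p = 0.791 with an estimated correlation) and endothelium (14 of 15 higher, median 0.20, 6 of 8 libraries, 0.00195; adjusted p = 0.784 with an estimated correlation) moved with these gene groups. Of 11 small leucine-rich proteoglycans, the family of Bgn, 10 lay higher and Bgn lower (median 0.27, camera adjusted p = 0.0297; adjusted p = 0.791 with an estimated correlation). Ogn had 0.55 (SE 0.15, adjusted p = 0.0503), Ecm2 0.26 (0.0545) and Lum 0.47 (0.179). Ogn, Lum, Dcn and Fmod also stand in the meningeal list, and the family's call ended without WT water replicate 1 (0.0695 in BgnKO vs WT averaged over drinks), the library labelled WT fructose replicate 1 (0.251), BgnKO water replicate 2 (0.0588) or 4 (0.0518), or BgnKO fructose replicate 2 (0.0742) or 4 (0.140). Nuclear-encoded oxidative phosphorylation, which includes Ndufs5, had a median of 0.06, a mean of -0.01 and an upward test (camera adjusted p = 0.0297; adjusted p = 0.805 with an estimated correlation). Its call ended without WT water replicate 4 (0.106), WT fructose replicate 2 (0.0849) or 4 (0.108), BgnKO water replicate 1 (0.0710) or 4 (0.0686), or BgnKO fructose replicate 1 (0.129) or 4 (0.0900). In all 21 of 47 lists passed with the preset correlation, 13 without BgnKO fructose replicate 4, 22 with the term for replicate 1, 24 in replicates 2 to 4, 0 with an estimated one and 5 with fry.

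**Figure D3:**
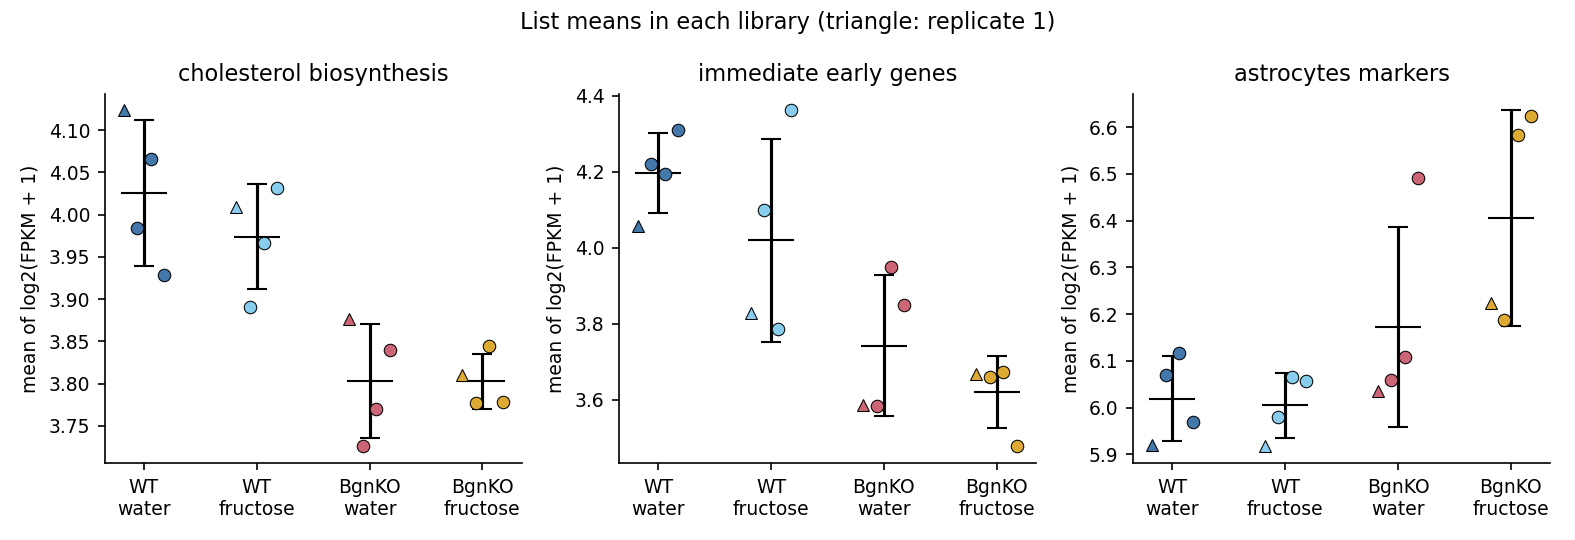
Mean log2(FPKM + 1) of the members of 3 lists (cholesterol biosynthesis, immediate early genes, astrocyte markers) in each of the 16 libraries by group, with the mean and SD of each group of 4; triangles mark replicate 1. In BgnKO the cholesterol and immediate early gene means lie under the WT mean of the same drink in 8 of 8 libraries and the astrocyte marker means above it in 8 of 8.

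The genes called in the averaged comparison were spread over the genome, with some close together. Of 592 called genes with a position 21 lay on the X chromosome, or 3.55%, against 3.42% of all tested genes with a position. On chromosome 1 between 185204117 and 191062932, 8 of 20 successive tested genes were called, among them Lyplal1 and Kcnk2. On chromosome 8 between 3621548 and 11008458, 7 of 20 were called, including Stxbp2 and Ccl25. The share of tested genes called was 8.68% (66 of 760) on chromosome 4 and 8% (52 of 650) on chromosome 8. The 38 tested genes near Bgn on the X chromosome did not move as a list (median -0.01, camera adjusted p = 0.918).

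**Figure D4:**
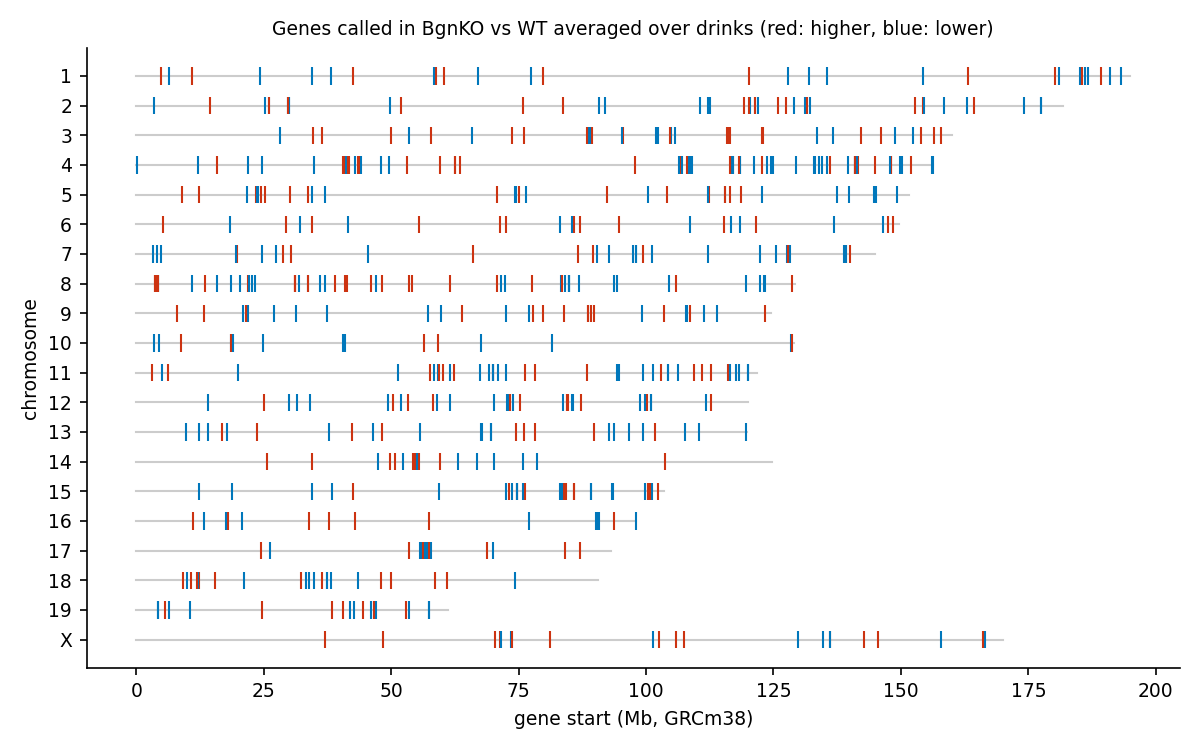
Position in megabases (GRCm38) of the genes called between BgnKO and WT averaged over drinks along chromosomes 1 to 19 and X; red marks are higher and blue marks lower in BgnKO. Of the 592 genes with a position, 21 lie on X.

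For fructose in WT mice limma called 1 of 12648 genes, Camk2a, the alpha subunit of the synaptic kinase CaMKII (chromosome 18, 60925618 to 60988152). It was listed at 0 in all 4 WT fructose libraries and at 781 to 1671 FPKM in the other 12, so no fold is given. Choroid plexus markers, striatal markers and immediate early genes lay lower on fructose, and ribosomal protein genes higher. With genes listed at 0 in a whole group left out, limma called 0, and 263 of all tested genes had an unadjusted p under 0.05. With the term for replicate 1 limma called 1, with 728 genes at an unadjusted p under 0.05, and in replicates 2 to 4 it called 3: Camk2a, Scoc (-1.09, adjusted p = 0.000242; -0.58 in all) and BC056474 (-0.78, 0.00635; -0.35 in all). In simulated data 54% of log2 changes of 0.5 were recovered.

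The genes of smallest unadjusted p all had an adjusted p of 1: Lypd6b (log2 fold -0.50, SE 0.11), Slc26a10 (0.78, SE 0.20), Fau (0.35, SE 0.10), Nmral1 (0.35, SE 0.10), Cys1 (0.27), Capn3 (0.57), Rps15a-ps4 (0.48), Mad2l1 (0.23) and Naca (0.34). Bgn had -0.05, Fmod -0.20, Dcn -0.46, Ttr, the transthyretin carrier made by choroid plexus, -1.15 (SE 0.83), Igf1 -0.02, Igf1r -0.04, Bdnf 0.01, Fkbp5 -0.01 and Fos -0.54. The fructose transporter Slc2a5 had 0.07 and the sugar-responsive Txnip -0.09. Fructose transport and metabolism did not move as a list of 9 genes, with 4 members higher and 5 lower; Gpd1 had 0.14, Slc2a9 0.08 and Aldoc 0.08.

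All 27 choroid plexus markers lay lower in WT fructose (median -0.59, 3 of 4 libraries, camera adjusted p = 4.89e-09; adjusted p = 0.562 with an estimated correlation), among them Kcnj13 (-0.94, SE 0.67), Aqp1 (-0.71, SE 0.53) and Ttr. That call ended without the library labelled WT fructose replicate 1 (adjusted p = 0.182 in WT fructose vs WT water), and 4 of the 15 lists passed without that library. These 4 were immediate early genes, BDNF and CREB signalling, ribosomal proteins and striatal markers. The 12 striatal markers lay lower (median -0.20, 4 of 4 libraries, camera adjusted p = 3.39e-06; adjusted p = 0.214 with an estimated correlation), with Drd1a at -0.28 (SE 0.11) and Tac1 at -0.32 (SE 0.17). Of 21 immediate early genes 19 lay lower (median -0.16, 3 of 4 libraries, 4.18e-05; adjusted p = 0.517 with an estimated correlation), and 47 of 55 ribosomal protein genes higher (median 0.12, 3 of 4 libraries, 0.000237; adjusted p = 0.562 with an estimated correlation), with Rpl7 at 0.36 (SE 0.13). The ribosomal call ended without WT water replicate 4 (adjusted p = 0.0537). BDNF and CREB signalling had a median of -0.03 and a mean of -0.53, which Camk2a sets (camera adjusted p = 0.00375; adjusted p = 0.214 with an estimated correlation; 0.289 in WT fructose vs WT water without genes listed at 0 in a whole group). Apart from Camk2a, 0 members of these lists passed over all genes or adjusted over the list alone. Across genes, the log2 fold fell with transcript length (Spearman's rho -0.313; genes are not independent replicates). With the preset correlation 15 lists passed, 8 without WT water replicate 3 and 4 without the library labelled WT fructose replicate 1. With the term for replicate 1 there were 16 and in replicates 2 to 4 10, and with an estimated correlation 0 passed and with fry 1.

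For fructose in BgnKO mice lists of genes passed with the preset correlation (19, of which 9 stayed without BgnKO fructose replicate 4), 0 with an estimated one and 0 with fry. Genes of oxidative phosphorylation, ribosomal proteins and myelin and markers of astrocytes and microglia lay higher on fructose, and neurotransmitter receptors lower. Limma called 0 of 12648 genes (smallest adjusted p = 0.318), with 1630 at an unadjusted p under 0.05. With the term for replicate 1 it called 0 (3177 at an unadjusted p under 0.05, smallest adjusted p = 0.0900), in replicates 2 to 4 it called 0 (0.0521), and with weights for each library 732, of which 368 were higher.

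The genes of smallest unadjusted p all had an adjusted p of 0.318: Pyurf (0.48, SE 0.09), the sorting receptor Sorcs3 (-0.31, SE 0.07), Ptpla (0.38, SE 0.08), Kctd16 in a merged entry (-0.38), Ddx46 (-0.45), Pcbd2 (0.49), Nudt14 (0.35), Oaz1 (0.58) and Tnik (-0.38). Bgn had -0.03, Ttr 0.61 (SE 0.83), Fmod -0.37, Dcn -0.19, Igf1 -0.07, Igf1r 0.04, Bdnf -0.04, Fkbp5 -0.03 and Fos -0.11, Slc2a5 -0.03 and Txnip 0.18. Fructose transport and metabolism had a median of 0.07 (9 genes, camera adjusted p = 0.415), with the sugar transporters Slc2a8 at 0.17 and Slc2a1 at 0.28.

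Of 64 oxidative phosphorylation genes 57 lay higher on fructose (median 0.15, 4 of 4 libraries, camera adjusted p = 1.45e-08; adjusted p = 0.395 with an estimated correlation), with Atp5e at 0.53 (SE 0.15) and Ndufa4 at 0.24 (SE 0.08). Of 55 ribosomal protein genes 48 lay higher (median 0.20, 4 of 4 libraries, 2.20e-08; adjusted p = 0.395 with an estimated correlation), with Rps9 at 0.42 (SE 0.13). Of 19 myelin genes 18 lay higher (median 0.23, 4 of 4 libraries, 6.77e-07; adjusted p = 0.395 with an estimated correlation), with myelin basic protein Mbp at 0.52 (SE 0.17) and Cnp at 0.31 (SE 0.10). Of 34 metabotropic glutamate, GABA and monoamine receptor genes 30 lay lower (median -0.17, 4 of 4 libraries, 2.41e-06; adjusted p = 0.395 with an estimated correlation), with the serotonin receptor Htr1b at -0.50 (SE 0.12). All 17 astrocyte markers (median 0.23, 3.54e-05; adjusted p = 0.512 with an estimated correlation) and all 18 microglial markers (median 0.25, 0.000109; adjusted p = 0.548 with an estimated correlation) lay higher. Of 11 CA1 markers 10 lay lower (median -0.24, 0.000879; adjusted p = 0.395 with an estimated correlation), with Wfs1 at -0.37 (SE 0.12). Of 20 genes of the unfolded protein response 15 lay higher (median 0.14, 0.00806; adjusted p = 0.395 with an estimated correlation), with the chaperone Hspa5 at 0.39 (SE 0.11), Sdf2l1 at 0.47 (SE 0.13) and Xbp1 at 0.28 (SE 0.08). No member of these lists passed over all genes. Adjusted over the list alone 6 myelin genes, 4 of the unfolded protein response and 1 each of ribosomal, receptor, astrocyte and microglial genes passed.

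With the preset correlation 19 of 47 lists passed in this comparison, 16 with the term for replicate 1, 27 in replicates 2 to 4, 0 with an estimated correlation and 0 with fry. Without BgnKO fructose replicate 4 camera called 10, 9 of them among the 19 with the same direction. The call of the unfolded protein response ended without BgnKO water replicate 4 (adjusted p = 0.0661 in BgnKO fructose vs BgnKO water) and that of microglial markers without BgnKO water replicate 1 (0.0511). Choroid plexus markers lay higher (26 of 27, median 0.49, 2 of 4 libraries, camera adjusted p = 0.00923; adjusted p = 0.800 with an estimated correlation), a call that ended without BgnKO water replicate 4 (0.614), BgnKO fructose replicate 2 (0.351) or 4 (0.719). With myelin, astrocyte and microglia scores as covariates the calls of ribosomal (0.0513), receptor (0.266) and CA1 genes (0.332) ended, and those of oxidative phosphorylation and the unfolded protein response stayed. Across genes the log2 fold fell with transcript length (Spearman's rho -0.396).

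**Figure D5:**
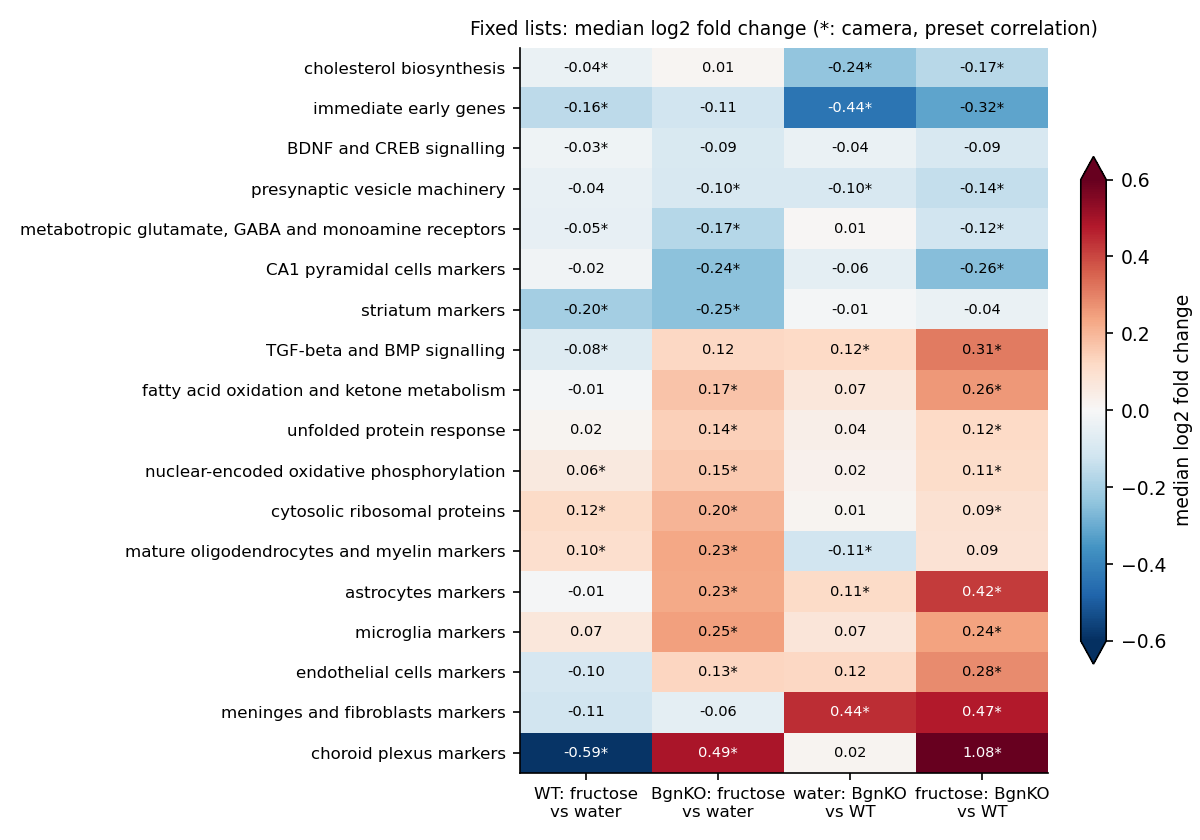
Median log2 fold change of 18 lists (rows, chosen after their values were seen) in the 4 pairwise comparisons (columns); a star marks a camera adjusted p under 0.05 with the preset correlation, and the colour scale ends at -0.6 and 0.6. With an estimated correlation 0 lists passed in any of the 4 comparisons.

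The difference between the fructose effects of the genotypes was tested as an interaction. Limma called Camk2a alone, with values listed at 0 in WT fructose, and 0 genes once such genes were left out, while 368 had an unadjusted p under 0.05. The next genes had an adjusted p of 0.999, among them the tubulin gene Tuba1c (1.02, SE 0.27), Pyurf (0.59, SE 0.13), Npc2 (0.47, SE 0.13), Ptpla (0.47), Galk1 (0.40), Mgat1 (0.29), Rbm5 (-0.31), Bms1 (-0.30) and Sorcs3 (-0.32). Ttr had 1.76 (SE 1.17), Fos 0.43, Dcn 0.27, Txnip 0.27, Fmod -0.17, Slc2a5 -0.11, Igf1r 0.08, Igf1 -0.06, Bdnf -0.05, Bgn 0.02 and Fkbp5 -0.02. Choroid plexus markers had an interaction median of 1.09, all 27 positive (camera adjusted p = 1.79e-10; adjusted p = 0.617 with an estimated correlation), astrocyte markers 0.24, all 17 positive (3.11e-06; adjusted p = 0.617 with an estimated correlation), and oxidative phosphorylation genes 0.09, 51 of 64 positive (0.000440; adjusted p = 0.633 with an estimated correlation). In all 13 lists passed, 4 without BgnKO fructose replicate 4 and 21 without BgnKO fructose replicate 1. The term for replicate 1 gave 12, replicates 2 to 4 10, and fry 0. In the fit with choroid plexus, meninges and astrocyte scores 8 lists passed, 0 of the 13 among them. Myelin, astrocyte and microglia scores gave 9, with 2 of the 13. With the term for replicate 1 limma called 1 gene, and in replicates 2 to 4 Camk2a and Scoc (0.97, adjusted p = 0.0290).

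Averaged over genotypes, fructose went with higher ribosomal protein, oxidative phosphorylation and myelin genes and lower receptor genes and striatal markers. Limma called Camk2a alone and 0 genes once genes listed at 0 in a whole group were left out, with 1367 at an unadjusted p under 0.05; it called 1 with the term for replicate 1 and 2 in replicates 2 to 4. The other genes of smallest unadjusted p had an adjusted p of 0.405: Bicd1 (-0.27), the thyroid hormone receptor Thrb (-0.33), Nmral1 (0.30), Lphn2 (-0.29), Shkbp1 (0.22), Gpr26 (-0.26), Rps15a-ps4 (0.41), Tnik (-0.27) and Lace1 (0.23). Bgn had -0.04, Fos -0.33, Dcn -0.32, Fmod -0.28, Ttr -0.27, Igf1 -0.05, Txnip 0.05, Slc2a5 0.02, Fkbp5 -0.02, Bdnf -0.01 and Igf1r 0.00. Ribosomal protein genes rose as a list (51 of 55 higher, median 0.15, 7 of 8 libraries, camera adjusted p = 2.29e-09; adjusted p = 0.479 with an estimated correlation), as did oxidative phosphorylation (60 of 64, median 0.11, 7 of 8 libraries, 6.06e-09; adjusted p = 0.487 with an estimated correlation) and myelin (19 of 19, median 0.18, 7 of 8 libraries, 4.19e-07; adjusted p = 0.487 with an estimated correlation). Receptor genes fell (30 of 34 lower, median -0.10, 8 of 8 libraries, 1.75e-06; adjusted p = 0.479 with an estimated correlation), as did striatal markers (10 of 12, median -0.23, 8 of 8 libraries, 2.42e-05; adjusted p = 0.335 with an estimated correlation). Adjusted over the list alone 3 receptor genes and 3 striatal markers passed, and 0 members of the other 3 lists. The log2 fold fell with transcript length (rho -0.439), a trend not removed. In all 16 of 47 lists passed, 15 with the term for replicate 1, 24 in replicates 2 to 4, 0 with an estimated correlation and 1 with fry, BDNF and CREB signalling, which holds Camk2a.

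Across 12648 genes, which are not independent replicates, the genotype effects on water and on fructose had a Pearson correlation of 0.62, and 0.54 in replicates 2 to 4. The fructose effects in WT and in BgnKO had a correlation of 0.13, and 0.04 in replicates 2 to 4. Neither pair of comparisons shares libraries.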

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

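The tests of library type in replicate 1, and of composition for the genes that stayed called, the comparison of folds with and without scores, and the splits counted by replicate 1, were chosen only after results were seen; the others were written down before they were run.

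A sample far from the others was found in 24 of 248 groups of 4 values, where chance flags about 1 in 20 groups. The library labelled WT fructose replicate 1 was low in Dcn (5.98 FPKM; others 41.0 to 46.4) and high in Bdnf (14.8; others 9.65 to 10.2). Its mean log2(FPKM + 1) was low for meningeal markers (1.61), small leucine-rich proteoglycans (1.69), fibrillar matrix (1.81), matrix proteases (3.78), CA1 markers (4.79) and thyroid hormone response (5.11). BgnKO water replicate 4 was high in markers of astrocytes (6.49), dentate gyrus granule cells (3.78), endothelium (3.54) and in circadian clock genes (4.00), and low in striatal markers (2.94). BgnKO water replicate 1 was low in Bgn (4.46 FPKM; others 7.19 to 7.60), neocortical markers (4.00) and presynaptic genes (6.56). Dcn was low in WT water replicate 2 (22.4; others 44.2 to 47.3) and high in BgnKO water replicate 2 (49.5; others 42.1 to 42.3). Interneuron markers were low in WT water replicate 2 (4.87), heat shock and NRF2 genes were high in WT fructose replicate 3 (4.90 and 4.46), and BgnKO fructose replicate 4 was low in immediate early genes (3.48) and high in NRF2 genes (4.70). Loci without a name took 46.8% of the FPKM in WT fructose replicate 2 and 59.3 to 59.9% in the other WT fructose libraries.

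A difference between groups, tested as the interaction, was found for 13 lists with the preset correlation and for 0 with an estimated one. The camera adjusted p was 1.79e-10 for choroid plexus, 3.11e-06 for astrocytes, 0.000440 for oxidative phosphorylation, 0.00115 for endothelium, 0.00274 for both TGF-beta and BMP signalling and myelin, 0.00319 for ribosomal proteins, 0.00642 for both metabotropic receptors and microglia, 0.00841 for fatty acid oxidation, 0.0126 for NRF2 genes, 0.0185 for CA1 (0.0795 with the replicate block) and 0.0292 for the unfolded protein response. Camk2a had a limma adjusted p of 2.98e-12 in the interaction, with 0 FPKM listed in the 4 WT fructose libraries. A value of 0 in all libraries of 1 group, for a gene at 781 FPKM or more in the other 12, has the form of a value left unreported by the quantification, which was not tested. Rn45s, at 0 in all BgnKO libraries, has the same form.

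A signal in data outside the comparisons was found in the loci without a name: of 1232 tested, 85 were called for BgnKO vs WT averaged over drinks, 49 higher and 36 lower, 29 on water, 67 on fructose, 1 for fructose in BgnKO and 0 in the other 3 comparisons.

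Replicate 1 of every group stood apart from replicates 2 to 4. Libraries or reads of another type in replicate 1 would give opposite-strand shares that do not overlap, and the gap was 11.9 percentage points. Lower depth in replicate 1 would weaken the separation among strongly expressed genes, but the first component had a correlation of 0.976 with replicate 1 among genes with at least 20 FPKM, so depth alone is excluded by this test. No biological explanation was tested, since each group holds 1 such library.

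Genes changed between BgnKO and WT averaged over drinks could stem from the loss of Bgn or from differences between the mouse lines or dissections. Segments of another strain in the knockout line remain possible: 48.0% of 571 called autosomal genes had a called neighbour, above the central range of 10000 random lists (34.3 to 44.0%, highest 49.0%), a test that shared regulation of neighbours would also pass. A segment around Bgn alone is excluded by 3.55% of called genes on X, and merged or multi-locus genes by 9.35% (8.10% of all tested genes). Different shares of choroid plexus, meninges and astrocytes are left open, as 27.4% of the genes stayed called with these 3 scores, but the 458 that did not kept a median of 72.5% of their fold while standard errors grew by a factor of 1.45. The 173 that stayed called decide nothing either, because both fits used the same libraries.

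Fixed lists that moved between BgnKO fructose and BgnKO water could reflect fructose or the make-up of single samples. The library BgnKO fructose replicate 4 alone remains a possible cause of many of them, since only 9 of 19 lists stayed called without it. A length trend is excluded as the whole cause: 14 of 19 stayed called once it was removed (18 before, same test). One with GC content (rho 0.336) was not removed. A larger share of glia remains possible, since 3 of the 16 other lists stayed called with myelin, astrocyte and microglia scores, and the 13 others kept a median of 17.7% of their median fold, a change that a response of glia to fructose would also give.

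Other splits of the same libraries tested whether chance can be excluded for the counts of genes. For BgnKO water vs WT water 1 of 35 splits, the real one, gave as many genes (49, highest other 0). So did 1 of 35 for BgnKO fructose vs WT fructose (475, highest other 1). Of these splits 20 part the 2 replicate 1 libraries as the real one does. Of those, 1 gave as many in either comparison, too few for a share under 0.05, so chance is left open. For BgnKO vs WT averaged over drinks 3 of 100 splits gave as many (631; highest other 967). The split with 967 put all 4 replicate 1 libraries on one side, and within replicates 2 to 4 limma called 1590 genes. Chance is not excluded for WT fructose vs WT water (2 of 35 splits; 1, highest other 2, with both replicate 1 libraries on one side; 1 of the 8 that part all 4 pairs, too few for a share under 0.05), the interaction (13 of 100 splits; 1, highest other 171) or fructose vs water averaged over genotypes (13 of 100 splits; 1, highest other 2). For BgnKO fructose vs BgnKO water (0 genes) 35 of 35 splits gave as many, so they cannot test it. The highest other, with 492, grouped BgnKO water replicate 4 with BgnKO fructose replicates 1, 3 and 4 and points to a structure of the samples other than the drink. The split with 171 set all 4 replicate 1 libraries on one side; within replicates 2 to 4 the interaction gave 2 genes.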

How the results depend on the processing

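Directions of called genes were kept almost everywhere, while counts of genes and lists moved with the model and the libraries. Over all single values, those printed in the text included, 5013 stayed the same, 179 lost and 40 gained their call. A further 233 turned their sign while called in neither fit, and 1 turned its sign with a call in at least 1 fit. The cause of a change was not tested unless a cause is named. The settings that name replicate 1, replicates 2 to 4, values listed at 0, a pair of libraries left out, or more than 1 marker score were chosen after seeing the data. Scaling alternatives shifted the median of all genes by less than 0.1. Depth is unknown for FPKM, so its limit on the weak genes was not measured.

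The genes called for BgnKO water vs WT water (49) became 26 with a filter of 5 FPKM, which tests fewer genes, 330 with array weights, 126 with the term for replicate 1, 79 in replicates 2 to 4 and 86 with choroid plexus, meninges and astrocyte scores. For BgnKO fructose vs WT fructose (475) the same settings gave 313, 1924, 2190, 1377 and 31. There the choroid plexus score alone gave 282, myelin, astrocyte and microglia scores 20, the fit of only 2 groups, which holds fewer samples, 87, and leaving out the library labelled WT fructose replicate 1 with BgnKO fructose replicate 4 137. For BgnKO vs WT averaged over drinks (631) a filter of 5 FPKM gave 414, array weights 2142, the term for replicate 1 2279, replicates 2 to 4 1590 and the glial scores 53. For BgnKO fructose vs BgnKO water (0) array weights gave 732. For WT fructose vs WT water, the interaction and fructose vs water averaged over genotypes (1 each, Camk2a) replicates 2 to 4 gave 3, 2 and 2, and leaving out genes listed at 0 in a whole group gave 0, 0 and 0 by its construction.

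Replicate number as a block gave 125 genes for BgnKO water vs WT water, 2483 for BgnKO fructose vs WT fructose and 2508 for BgnKO vs WT averaged over drinks. Of 16 libraries 7 correlated best with their own number in another group, replicate 1 of every group among them. For fructose in WT and in BgnKO the replicate block gave 1 and 0 genes and 16 lists each. It added endothelial markers in WT (adjusted p = 0.0201), ended 3 list calls in BgnKO, CA1 in the interaction and neuropeptides for fructose averaged over genotypes (0.109), and changed no other call in these 4 comparisons.

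The lists called with the preset correlation (15 for WT fructose vs WT water, 19 for BgnKO fructose vs BgnKO water, 13 for BgnKO water vs WT water, 23 for BgnKO fructose vs WT fructose, 13 for the interaction, 21 for BgnKO vs WT averaged over drinks and 16 for fructose vs water averaged over genotypes) became 0 in all 7 with an estimated correlation, and 1, 0, 1, 10, 0, 5 and 1 with fry. Without the library labelled WT fructose replicate 1 and BgnKO fructose replicate 4, 4 passed for WT fructose vs WT water. For BgnKO fructose vs BgnKO water 10 passed, and 8 for BgnKO fructose vs WT fructose. The interaction gave 7, 2 of the 13 among them. Averaged, BgnKO vs WT gave 9 and fructose vs water 10. With choroid plexus, meninges and astrocyte scores 17 passed for WT fructose vs WT water, 6 for BgnKO fructose vs BgnKO water, 2 for BgnKO water vs WT water, 5 for BgnKO fructose vs WT fructose, 8 for the interaction, 5 for BgnKO vs WT averaged over drinks and 9 for fructose vs water averaged over genotypes. Of the lists called without scores, 12, 4, 2, 1, 0, 2 and 9 were among them, in this order. With myelin, astrocyte and microglia scores 10, 8, 8, 8, 9, 5 and 8 passed, 9, 3, 6, 5, 2, 4 and 5 of the lists called without scores among them. The choroid plexus score gave 11, 12 and 13 for BgnKO fructose vs BgnKO water, BgnKO fructose vs WT fructose and BgnKO vs WT averaged over drinks. Array weights gave 11 for BgnKO fructose vs BgnKO water, and for BgnKO water vs WT water a filter of 5 FPKM gave 6 and quantile normalization 7.

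Leaving out each library in turn gave 30 to 57 genes for BgnKO water vs WT water, 147 to 940 for BgnKO fructose vs WT fructose, 392 to 1061 for BgnKO vs WT averaged over drinks, 0 to 0 for BgnKO fructose vs BgnKO water and 1 to 1 for the other three. Lists ran from 4 to 19 for WT fructose vs WT water, 10 to 25 for BgnKO fructose vs BgnKO water, 5 to 13 for BgnKO water vs WT water, 11 to 26 for BgnKO fructose vs WT fructose, 4 to 21 for the interaction, 13 to 23 for BgnKO vs WT averaged over drinks and 13 to 17 for fructose vs water averaged over genotypes. The difference in Bgn FPKM, BgnKO vs WT, of -9.51 ran from -11.0 to -8.34. The correlation of the fructose effects turned from 0.13 to -0.24 (-0.243) with choroid plexus, meninges and astrocyte scores. Not run were a pseudocount for that Bgn difference, which uses no logarithm, the choroid plexus score for it, and the fit of only 2 groups for single genes.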

Other observations

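No test in this part was chosen after results were seen, and no explanation is offered. Several fixed lists outside the groups described above passed in the genotype comparisons. On fructose, complement and microglial activation lay higher in BgnKO (13 genes, median 0.42, camera adjusted p = 0.0103), as did interferon response (14 genes, 0.29, 0.0103), fibrillar matrix (15 genes, 0.38, 0.0210), matrix proteases and inhibitors (15 genes, 0.12, 0.0240) and NRF2 and oxidative stress response (21 genes, 0.0101). On water, fibrillar matrix (0.17, 0.0196), interferon response (0.17, 0.0258), ependymal markers (14 genes, 0.19, 0.0378) and pericyte markers (14 genes, 0.32, 0.0378) lay higher, and glucocorticoid response (16 genes, -0.13, 0.0441) and circadian clock genes (18 genes, -0.04, 0.0378) lower. Each of these calls ended when some single library was left out, and with an estimated correlation 0 passed.

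With fructose in BgnKO, interneuron markers (15 genes, median -0.17, camera adjusted p = 0.00687), neuropeptides (16 genes, 0.0327; 0.0943 with the replicate block), ionotropic glutamate receptors and scaffolds (22 genes, 0.0362; 0.122 with the block) and neocortical markers (15 genes, 0.0473; 0.110 with the block) lay lower. With fructose in WT, dentate gyrus granule cell markers (16 genes, 0.14, 0.00420), CA3 and CA2 markers (16 genes, 0.0257) and the heat shock response (13 genes, 0.0367) lay higher. None of these passed with an estimated correlation.

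Other fixed lists passed in none of the 7 comparisons. The lowest and highest camera adjusted p were 0.154 and 0.848 for fructose transport and metabolism (9 genes), 0.184 and 0.946 for insulin and IGF signalling (24), 0.352 and 0.993 for glycolysis (21), 0.145 and 0.995 for Toll-like receptor and NF-kB signalling (10), 0.155 and 0.956 for thyroid hormone response (12), 0.124 and 0.922 for genes near Bgn on the X chromosome (38), 0.610 and 0.907 for basement membrane (13), 0.502 and 0.923 for the perineuronal net (11), 0.117 and 0.453 for oligodendrocyte precursor markers (14) and 0.330 and 0.995 for thalamus and habenula markers (14). Adult neurogenesis and proliferation (12 genes) had a lowest adjusted p of 0.4201.

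The correlation across genes of the genotype effects on both drinks (0.62) was reached in 2 of 100 random splits, with a highest other of 0.65, and that of the fructose effects (0.13) in 28 of 100, with a highest other of 0.66. The first 3 principal components held 32.7, 21.1 and 11.1% of the variance.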
